A study of Rattus norvegicus with 8 samples.

How the data were processed

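Whole blood RNA was measured in 8 male Wistar rats, 4 of which had eaten a normal diet and 4 a high-fat diet over 8 weeks. Per the labels' protocols, blood was taken after an overnight fast and mixed with a phenol reagent. Total RNA was extracted, column-purified, amplified and biotin-labelled for Affymetrix 3' expression arrays. These arrays measure each transcript with 1 or more probe sets, groups of short probes near its 3' end. The labels call the arrays of a group biological replicates, and each was treated as a separate animal. Groups and replicate numbers came from the sample titles. A further diet group named in the labels, which received mulberry leaf powder with the high-fat diet, is not analysed here.

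The values used were those of the table the authors deposited, whose levels read as log2 intensities, from 5.19 to 15.25 in each of the 8 arrays. How the authors corrected the background, normalized the arrays and combined probes is not given in the sources used here. The medians of all 8 deposited columns were 6.60. Between arrays, the deposited values of a probe set differed very little. The median SD of a probe set over the 8 arrays was 6.07e-06, the 99th percentile of these SDs was 4.13e-04, and the largest was 0.139. No probe set had a range over the 8 arrays reaching 1.5-fold, and 5 of them had a range over 0.1. The deposited differences are therefore not log2 ratios of RNA amount, and how strongly they were compressed can differ between probe sets. For this reason no fold changes are given. Differences are stated as high-fat minus normal in deposited units, and as multiples of the pooled SD within the groups of that probe set, called within-group SDs. Signal over background of single probe sets was not analysed here, so the number of arrays is the stated limit on precision.

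The table held 31099 probe sets. The 57 control probe sets were left out of the tests, which left 31042. Gene names came from the platform annotation. It gave 1 gene symbol for 20826 of the tested probe sets, several for 436 and none for 9780, which are unnamed here. Of those with 1 symbol, 20758 matched a gene of the GRCr8 annotation by gene number, and none of these symbols had changed. Coordinates of that assembly were not used. No pair of arrays held identical values, 1 probe set had an SD of 0, and 2016 had an SD under 1e-06.

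Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, high-fat against normal, no covariates), with Benjamini-Hochberg adjustment over 31042 probe sets and a threshold of 0.05. For gene lists, each of 14217 genes was represented by the probe set with the highest mean over the 8 arrays. The 38 lists cover 11 blood cell or tissue types and 27 pathways, and were written before the data were examined, as were the tests and the rule for named genes. They held 1013 distinct members, of which 843 had a probe set named here. Members whose group means differed by at most 1e-12, the rounding of the arithmetic, were counted as equal, which applied to Hbb and Gabarap. Camera, which compares the test statistics of a list with those of all other genes, was run with a preset inter-gene correlation of 0.01 and adjusted over the 38 lists. The erythroid and heme lists shared 4 measured genes, Alas2, Tfrc, Fech and Slc25a37. Mean levels of lists were compared with an exact permutation test over all assignments of 4 against 4 animals, two-sided, for which the smallest possible p is 0.0286. The same test was applied to the neutrophil list minus the T and B cell lists, to the erythroid list, and to the 3' minus 5' level of the actin and Gapdh control transcripts. For plots and comparisons of single animals, each gene was scaled to a mean of 0 and an SD of 1 over the 8 arrays before averaging over a list. This is called the scaled level.

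Genes were named by a rule. Where fewer than 10 probe sets passed the threshold, the 10 with the smallest p were named, as values and not as changes. For each list past camera, the 3 members with the smallest p in the direction of the list were named, plus the member with the smallest p in the other direction if it passed. For each other cell type list, the 2 members with the smallest p were named. Each gene was represented there by its probe set with the smallest p, and only probe sets with 1 symbol were eligible. Xpo7 and the genes with the largest spread were singled out after their values were seen.

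The alternatives tried were quantile normalization on top of the deposited values, centring each array on its median, filters on dim probe sets, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each animal, a further requirement of 1.5-fold, rank products with 100 random columns, Welch's test, 2 cell type covariates, camera with an estimated correlation, fry, and the mean over all probe sets of a gene. A floor planned for linear values was not needed. Alternatives added after seeing the data were scaled levels, a filter on SDs under 1e-06, the erythroid list without Xpo7, and the first principal component of the within-group deviations as a covariate. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

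The tests were tried on simulated data with the real mean and within-group SD of each of the 31042 probe sets, 4 against 4 arrays, in which 50 probe sets were shifted by each of 4 sizes. At a shift of 4 within-group SDs limma recovered 20 of 50, at 8 it recovered 47, at 16 it recovered 49 and at 32 all 50, with 12 calls among unshifted probe sets. Welch's test recovered 9, 37, 50 and 50, with 5 calls among unshifted probe sets. All shifted probe sets were in 1 table with independent noise, and the larger shifts ease the adjustment for the smaller ones. Recovery can therefore be lower where few probe sets change. Rank products recovered 103 of the 200 shifted probe sets and called 433 unshifted ones, so its calls on these values are not selective. With independent genes, camera recovered all 3 lists shifted by 1 within-group SD among the 38 lists over 14217 genes. There were 0 false calls, in a count without the heme and iron list, which shares genes with the shifted erythroid list.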

Results

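Whole blood from 4 rats on a normal diet and 4 rats on a high-fat diet, each fed for 8 weeks, was profiled on 8 arrays with 31042 probe sets for transcripts. Whole blood RNA comes from red cell precursors that still hold RNA, platelets and all white cells, so levels of a gene can follow both its expression and the share of the cells that express it. The series title names mulberry leaf ingestion and blood gene expression as its subject. The arrays used here hold its comparison of a high-fat with a normal diet.

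No probe set was distinguished between the diets. With limma, 0 of 31042 probe sets passed an adjusted p of 0.05, 0 higher and 0 lower in the high-fat group, and the smallest adjusted p was 0.736. At an unadjusted p under 0.05 there were 699 probe sets, 295 higher and 404 lower, against 1552 expected by chance alone. Rank products, which also called many unshifted probe sets in simulated data, gave 250. The 4 high-fat values lay entirely above or below the 4 normal values in 448 probe sets, 1.44% of all, where chance gives 2.86%.

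The 10 genes with the smallest p are therefore given as values. Camk2a, a subunit of a calcium- and calmodulin-dependent kinase, had a mean level of 6.34 in both groups and was 2.84e-05 ± 2.80e-06 (SE, n = 4 and 4) higher in the high-fat group by limma, or 7.03 within-group SDs, with an adjusted p of 0.736. Of the other 9, all with an adjusted p of 1 by limma, Plod1 (a collagen lysyl hydroxylase) stood 5.17 within-group SDs above normal, Kcnab2 (a potassium channel subunit) 5.41, Shox2 (a homeobox factor) 4.19 and Gstt3 (a glutathione transferase) 3.74. The cytokine Il6 had a difference of -4.24 within-group SDs, Ropn1l -3.93, the cartilage collagen chain Col10a1 -3.92, the synaptic protein Nrxn2 -3.68 and the elongation cofactor Eaf1 -3.50. Most of these genes had low levels. Normal means of Ropn1l (5.37), Shox2 (5.76) and Il6 (5.87) lay below the 25th percentile of the arrays, 6.22. Those of Col10a1 (6.27), Camk2a, Kcnab2 (6.48), Nrxn2 (6.49) and Eaf1 (6.56) lay below the median, 6.60. Plod1 (6.83) and Gstt3 (7.75) lay above it. Other probe sets of 5 of these genes did not repeat the values. The 3 further probe sets of Camk2a stood at 1.54, -0.135 and -0.115 within-group SDs, those of Kcnab2 at -1.70, -1.14 and 0.689, and those of Shox2 at 0.741 and 0.600. The second probe sets of Nrxn2 and Eaf1 had the opposite sign, at 0.823 and 0.652. Centring each array on its median moves every difference alike, by -6.60e-05, which is more than the differences of Camk2a, Plod1, Kcnab2 and Shox2 and puts them below 0.

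There were 7 lists that differed from all other genes by camera, and none of those calls held with an estimated inter-gene correlation. Fry, which tests each list against no change and not against other genes, called 0 lists. Red cell genes were the list among them that also had an exact p under 0.05 for its mean level before adjustment. Of 23 measured members of the erythroid list, 18 were higher in the high-fat group, 4 lower and 1 equal, with a camera adjusted p of 3.36e-05. With an estimated correlation the adjusted p = 0.153. No member passed limma, adjusted over all genes or adjusted over the list alone. Hemgn, a nuclear protein of red cell precursors, had a level of 10.06 ± 0.0012 (SD, n = 4) in the normal group and 10.07 ± 0.0015 in the high-fat group. Its difference was 0.00360, or 2.63 within-group SDs, and all 4 high-fat animals lay above all 4 normal ones. Slc4a1, the anion exchanger of the red cell membrane, stood 1.71 within-group SDs above normal and Klf1, a transcription factor of the red cell lineage, 1.59. A second probe set of Slc4a1 stood at 0.647. The median member stood at 0.551 within-group SDs, and at 0.355, 0.289 and 1.09 without normal replicate 3, high-fat replicate 3 and high-fat replicate 4. Quantile normalization on top ended the call (adjusted p = 0.775) and turned the differences of Hemgn and Klf1 to -0.00142 and -2.81e-04. It put the difference of Slc4a1 at 0, as for many named genes, because the arrays differ too little for many probe sets to change rank. A call lost under it, here and for the lists below, therefore decides little about a list. The same holds for calls with centring, whose shift can favour lists of large spread.

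The mean level of the erythroid list was 9.92 ± 5.53e-04 (SD, n = 4) in the normal group and 9.93 ± 0.00874 in the high-fat group. The difference of 0.00597 reached the smallest p that the exact permutation test can give, 0.0286, and was 0.543 after adjustment over the 38 lists. Adjusted values under 0.05 would need 22 lists at that smallest p. Of this difference, 88.0% came from Xpo7, a nuclear transport receptor. Without Xpo7 it was 7.48e-04, with an exact p of 0.0857, and without high-fat replicate 1, whose list level was highest, it was 0.00160. The heme and iron list, which shares 4 measured genes with the erythroid list, had 14 of 21 members higher (camera adjusted p = 0.00556, and adjusted p = 0.153 with an estimated correlation). No member passed limma, adjusted over the list alone included. Urod and Alad, enzymes of heme synthesis, stood 2.0 and 1.90 within-group SDs above normal, and the iron regulator Ireb2 1.62. The call was lost without high-fat replicate 4 (adjusted p = 0.102), although the median member rose from 0.328 to 0.516 within-group SDs, and with quantile normalization on top (0.817). The median was 0.110 without high-fat replicate 1, 0.537 without normal replicate 1 and 0.494 without high-fat replicate 3.

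Genes of the interferon response had 26 of 33 members higher in the high-fat group, with a camera adjusted p of 1.65e-06 and an adjusted p = 0.153 with an estimated correlation. None passed limma, adjusted over the list alone or over all genes. The antiviral genes Cmpk2, Isg20 and Rsad2 stood 1.90, 1.89 and 1.46 within-group SDs above normal. The scaled level of this list was -0.289 ± 0.826 (SD, n = 4) in the normal group and 0.289 ± 0.356 in the high-fat group, a difference within the spread of the animals (exact p = 0.286). The lowest animal was normal replicate 3, at -1.34, and without it the list was no longer called by camera (adjusted p = 0.104), with the median member at 0.256 within-group SDs against 0.557. Without normal replicate 2 or 4 the median was 0.920 or 0.907. With quantile normalization on top the list was still called by camera (adjusted p = 0.0129), but the median member fell to 0.00331 within-group SDs.

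Among white cells, the list of natural killer and cytotoxic cells had 22 of 24 members higher in the high-fat group (camera adjusted p = 6.59e-05, and adjusted p = 0.434 with an estimated correlation). Il2rb, a receptor chain for interleukin signals, stood 1.21 within-group SDs above normal, the chemokine Xcl1 0.975 and the activating receptor Klrk1 0.921. High-fat replicate 4 was at a scaled level of 1.61 on this list, and the other high-fat animals lay between -0.308 and -0.0803. Without that animal the adjusted p was 0.351 and the median member at 0.202 within-group SDs, against 0.686. The T cell list had 19 of 23 members lower (camera adjusted p = 0.0351, and adjusted p = 0.434 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, had a difference of -2.25 within-group SDs, the costimulator Icos -1.37 and the T cell factor Gata3 -1.25. The brighter probe sets of Cd3e and Icos used in the list test stood at -0.275 and -1.17. A further probe set of Icos stood at -0.0538 and a second one of Gata3 at -0.814. In this list normal replicate 3 lay at -1.08 and the 3 other normal animals between 0.606 and 0.620. The call was lost when any of normal replicates 1, 2 and 4 or high-fat replicates 1, 3 and 4 was left out, with adjusted p from 0.0731 to 0.337, and with quantile normalization (0.964) or centring (0.0757). The median member, -0.275 within-group SDs, was about as low without normal replicate 1 (-0.272), high-fat replicate 1 (-0.310) or high-fat replicate 3 (-0.334), and nearer 0 without normal replicates 2 and 4 (-0.143 and -0.176) or high-fat replicate 4 (-0.210). Without normal replicate 3 it was -1.28, with an adjusted p of 2.70e-08, and without high-fat replicate 2 it was -0.537 (adjusted p = 0.00421). No member of either list passed limma, adjusted over the list alone included.

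**Figure D1:**
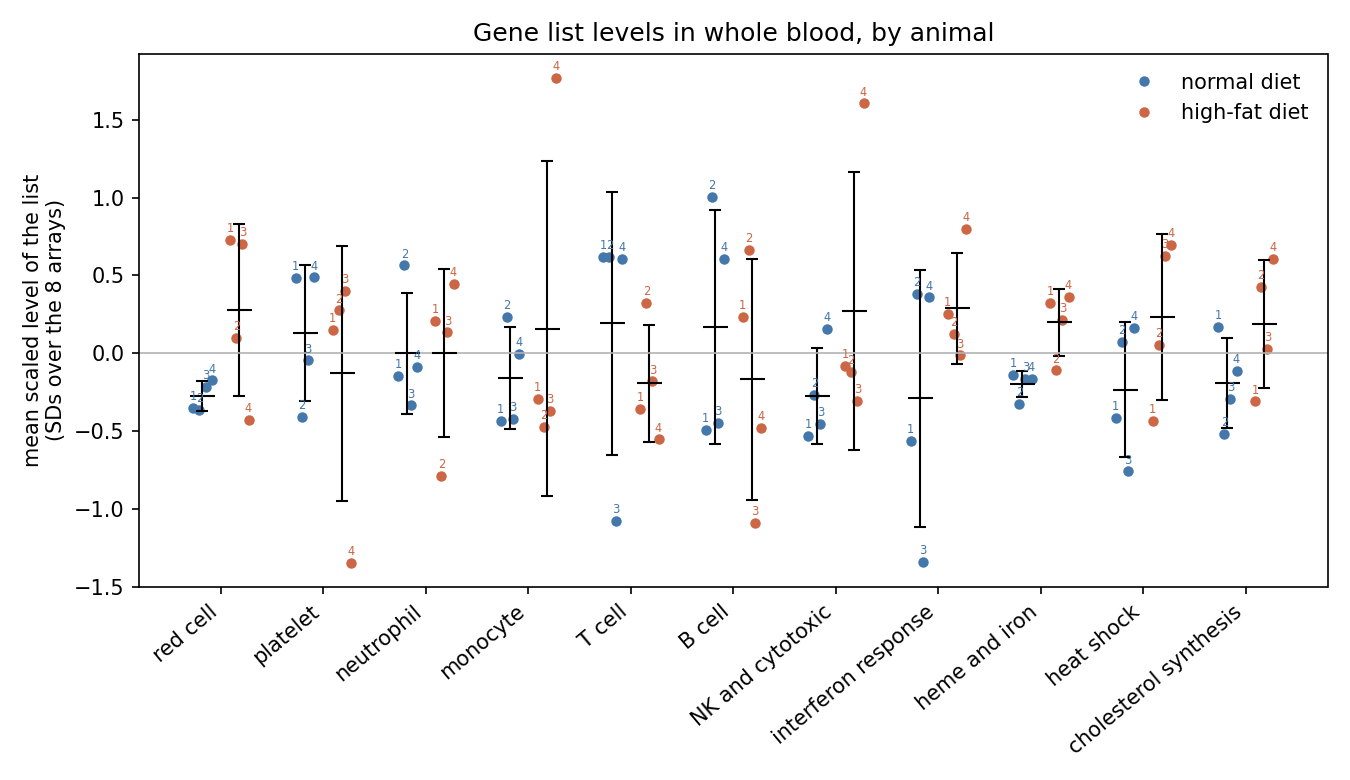
Mean scaled level (SDs over the 8 arrays) of 11 gene lists in each animal, with the replicate number above each point, blue for the normal and orange for the high-fat diet. Black lines are the group mean ± SD (n = 4); the high-fat means of the monocyte and cytotoxic lists rest on replicate 4, at 1.77 and 1.61.

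Heat shock genes had 12 of 14 members higher in the high-fat group (camera adjusted p = 0.00810, and adjusted p = 0.153 with an estimated correlation). The chaperone genes Hsph1, Dnajb1 and Dnaja1 stood 1.90, 1.63 and 1.36 within-group SDs above normal, and the probe set of Dnaja1 in the list test 0.871. Second probe sets of Hsph1 and Dnajb1 stood at 1.62 and 0.537. Leaving out normal replicate 3, high-fat replicate 3 or high-fat replicate 4 ended the call, with adjusted p of 0.189, 0.0605 and 0.127, as did quantile normalization (0.775). The median member, 0.466 within-group SDs, was then 0.235, 0.433 and 0.335 without these animals, and 0.829 without normal replicate 4. Genes of cholesterol synthesis had 14 of 20 members higher (camera adjusted p = 0.0109, and adjusted p = 0.153 with an estimated correlation). Srebf2, the transcription factor of the sterol pathway, and Mvk, mevalonate kinase, stood 3.04 and 3.03 within-group SDs above normal, and Sc5d, a late enzyme of the pathway, 2.24. A second probe set of Srebf2 stood at 0.441. The list test used brighter probe sets of Mvk and Sc5d, which stood at -1.02 and -0.0126, so both count there among the 6 lower members. This call was lost without normal replicate 2 or 3 or high-fat replicate 2 or 4, with adjusted p from 0.0590 to 0.161. The median member, 0.404 within-group SDs, was 0.294, 0.289, 0.369 and 0.183 in that order. The call was also lost with quantile normalization (0.964), with centring (0.814) and among the brighter 50% of probe sets (0.0675). No member of these lists passed limma, adjusted over the list alone included.

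Other genes of lipid and energy metabolism were not called as lists on the deposited values. Fatty acid oxidation had 21 of 33 members higher (camera adjusted p = 0.357), lipogenesis 12 of 21 (0.374), lipid uptake and storage 13 of 22 (0.283) and cholesterol efflux 9 of 16 (0.942). Among the lists of glucose and energy use, glycolysis had 10 of 17 members higher (camera adjusted p = 0.374), the citric acid cycle 8 of 19 (0.999), oxidative phosphorylation 15 of 35 (0.942) and insulin signalling 16 of 29 (0.942). Lipogenesis was called in 1 of 18 alternatives, among the brighter probe sets (adjusted p = 0.0308). Without normal replicate 3 the citric acid cycle and oxidative phosphorylation were called (0.0305 and 0.0275), with medians of -0.539 and -0.686 within-group SDs. The mean level of the lipid uptake and storage list was 2.19e-04 higher in the high-fat group, with an exact p of 0.0286 and 0.543 after adjustment. Of this difference 97.2% came from the fatty acid transporter Cd36, singled out after its value was seen, and the scaled level gave an exact p of 0.629. Without high-fat replicate 1 the difference was 1.15e-04 (exact p = 0.0286). This and the erythroid list were the 2 of 38 with an exact p under 0.05 before adjustment. After it the count was 0, which the smallest p of the test all but fixes. On scaled levels, the heme and iron list and the cell cycle list had an exact p of 0.0286, and neither passed after adjustment (0.543).

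Inflammatory genes of the NF-kB pathway had 17 of 35 members higher (camera adjusted p = 0.942). Il6 was the member of any list with an adjusted p under 0.05 when adjusted over the list alone, at 0.0315 by limma, and its adjusted p over all probe sets was 1. Its level of 5.87 lies below the 25th percentile of each array, 6.22. Toll-like receptor signalling had 17 of 23 members higher (camera adjusted p = 0.325), class II antigen presentation 2 of 10 (0.302) and complement and coagulation 7 of 21 (0.942). For stress and signalling lists, autophagy and lysosome had 19 of 26 members higher and 1 equal (camera adjusted p = 0.0530, and under 0.05 in 8 of 18 alternatives), antioxidant response 19 of 29 (0.113), immediate early genes 16 of 23 (0.165), glucocorticoid response 11 of 20 (0.165), endoplasmic reticulum stress 16 of 24 (0.220) and circadian clock 5 of 17 (0.302). For lists of basic cell functions, the cell cycle had 21 of 32 members higher (camera adjusted p = 0.0629), the cytosolic ribosome 8 of 33 (0.374), the proteasome 10 of 27 (0.384), apoptosis 12 of 22 (0.404) and splicing 17 of 29 (0.686). By camera, the ribosome and proteasome were called without normal replicate 3, with medians of -0.944 and -0.726 within-group SDs (adjusted p = 7.47e-04 and 0.00158). The ribosome was also called without high-fat replicate 4 (-0.484, 0.0209). Endoplasmic reticulum stress was called without normal replicate 4 (0.541, 0.0211). The antioxidant and glucocorticoid lists were called without high-fat replicate 2 (0.288 and 0.294, 0.0133 and 0.0286). Apart from Il6, no member of the 38 lists passed limma, adjusted over the list alone.

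The remaining cell type lists did not pass camera either. Monocyte genes had 18 of 21 members higher (adjusted p = 0.0512). This list was called in 10 of 18 alternatives, and without high-fat replicate 4 its median member stood at -0.397 within-group SDs (adjusted p = 0.0833). Vcan, a matrix proteoglycan made by monocytes, stood 2.28 and Cx3cr1, a chemokine receptor, 0.840 within-group SDs above normal. The probe set of Vcan in the list test stood at 0.617. B cell genes had 18 of 19 members lower (adjusted p = 0.113), with Blk at -1.32 and Cr2 at -0.928, and the list was called in 4 of 18 alternatives. Their probe sets in the list test stood at -0.189 and -0.383, and 2 further probe sets of Cr2 had the opposite sign, at 0.727 and 0.639. Platelet genes had 14 of 19 lower (adjusted p = 0.265), with the adhesion receptor Selp at -2.37 and Clu at -0.943, while the brighter probe sets used in the list test stood at 0.0132 and 0.0528. Without normal replicate 2 the platelet list was called (adjusted p = 0.0460), with its median member at -0.480 within-group SDs, against -0.186. Neutrophil genes had 12 of 22 higher (adjusted p = 0.891), with Retnla at -0.997 and Arg1 at 1.01. Genes of eosinophils, basophils and mast cells had 13 of 19 higher (adjusted p = 0.148), with the granule protein Prg2 at 2.40 and the histamine-forming enzyme Hdc at 1.52. That list was called without normal replicate 3 (adjusted p = 0.0428), with its median member at 0.583 within-group SDs, against 0.291. Dendritic cell genes had 9 of 13 higher (adjusted p = 0.113), with Bst2 at 1.32 and Irf7 at 1.22. For tissues outside the blood, liver genes had 9 of 18 higher (adjusted p = 0.990), with Ahsg at -2.91 and Fgg at 1.39. Genes of fat, vessel and muscle had 8 of 20 higher (adjusted p = 0.999), with Fabp4 at -1.64 and Adipoq at -1.37 within-group SDs.

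The balance of neutrophils and lymphocytes showed no difference larger than the spread between animals. The neutrophil list minus the T and B cell lists was -0.713 ± 5.60e-04 (SD, n = 4) in the normal group and -0.713 ± 0.00139 in the high-fat group, a difference of 4.52e-05 (exact p = 0.971). Its sign turned without normal replicate 3 and without high-fat replicate 4, at -1.88e-04 and -6.46e-04. The 3' minus 5' level of the control transcripts, a sign of RNA quality, was 0.633 in both groups, with a difference of 1.85e-06 and an exact p of 0.83. That difference was also within the spread, with SDs of 7.92e-06 and 4.70e-06 (n = 4), and turned below 0 without normal replicate 1 or 3, at -3.50e-07 and -5.10e-07.

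The arrays did not divide by diet. The first principal component held 31.5% of the variance of the scaled levels, with loadings of 0.671 for normal replicate 3, 0.388 for high-fat replicate 3 and 0.201 for high-fat replicate 1, and loadings below 0 for the other 5 arrays. The second held 13.3%, with high-fat replicate 4 at -0.624. Normal replicate 3 was the array farthest from the mean in 25.1% of probe sets, and the other 7 arrays in 8.21% to 13.6% each.

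**Figure D2:**
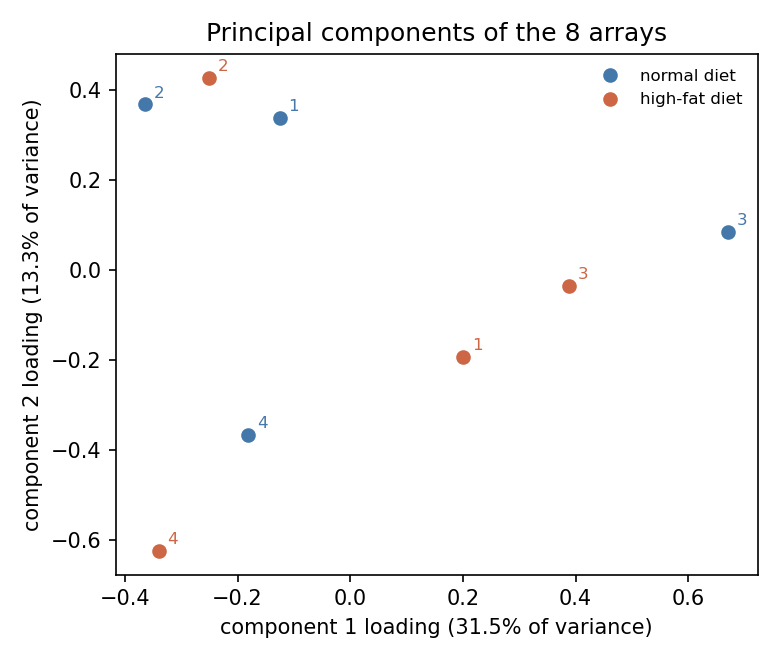
Loadings of the 8 arrays on the first and second principal components of levels scaled per probe set, with the share of variance on each axis and the replicate number beside each point. Points of both diets lie on both sides of 0 on the first component, with normal replicate 3 farthest out at 0.671.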

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

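All tests of explanations below were chosen after the result they measure was seen, except the test of signal contrast for normal replicate 3. Over the lists, named genes and summary values, 130 groups of 4 animals were examined for a single animal far from the other 3, and 17 (13.1%) had one. Chance alone gives about 1 in 20. The value given for each is the gap from that animal to its nearest neighbour, as a share of the range of its group.

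White cell lists set high-fat replicate 4 apart from the other 3 high-fat animals. It was highest on the monocyte list (0.919), the natural killer and cytotoxic list (0.881) and the dendritic list (0.866), and lowest on the platelet list (0.858). Its scaled level was 1.77 for monocytes and -1.35 for platelets. It was also the highest animal on lists that are not cell types, such as toll-like receptor signalling (1.06) and endoplasmic reticulum stress (0.993). The median of its tested probe sets, 6.60051, lay above those of the other 7 animals (highest 6.60037). A smaller share of platelet or red cell RNA would raise all white cell types alike. A test on the T and B cell lists alone did not decide this, since their mean was -0.516 in that animal against an SD of 0.703 over the normal animals. A second test was then set up in its place, on the gap between the monocyte and cytotoxic lists and the T and B cell lists. That gap was 2.20, where the highest of the other 7 animals was 0.324 and their SD 0.485. It contains the high monocyte and cytotoxic levels for which the animal was flagged, so a large gap was likely beforehand and decides nothing. Being the second of 2 attempts, it also weighs less than a test fixed in advance. The values show only that the T and B cell lists were not raised in this animal. A smaller share of platelet or red cell RNA and a different make-up of white cells both stay open. No biological explanation was tested, because the labels do not set the animal apart.

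The mean deposited level of the erythroid list in high-fat replicate 1 lay far above that of the other high-fat animals (0.972). That animal alone does not account for the order of the groups, since without it the exact p was 0.0286. More red cell RNA in all 4 high-fat animals stays open. The scaled level of replicate 4, -0.427, lies below all 4 normal animals, but its deposited level of 9.92128 lies above them (highest 9.92012). That deposited level includes Xpo7, and without Xpo7 the 4 high-fat animals no longer all lay above the normal ones. Another candidate explanation that stays open is the single gene Xpo7, whose removal left an exact p of 0.0857, while on scaled levels the difference was 0.553 with and 0.538 without it (exact p 0.143 for both). Its level was 8.86 in high-fat replicate 1, 8.48 in the 3 other high-fat animals, and 8.45 to 8.47 in the normal animals, and an effect of diet on Xpo7 or on a few red cell genes was not tested apart from this.

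T cell genes were lowest in normal replicate 3 (0.992), at a scaled level of -1.08. The same array was low for splicing (-1.61), the citric acid cycle (-1.28), the proteasome (-1.22), oxidative phosphorylation and the ribosome (both -1.13), and highest for liver genes (0.980). Lower signal contrast, in which dim probe sets read high and bright ones low, may account for this: dim minus bright medians differed by 1.32 SDs on this array, where the highest of the other 7 was 0.668 and their SD 0.443. The lists followed brightness only in part. The erythroid and platelet lists, with normal mean levels of 9.92 and 9.27, stood at -0.215 and -0.0453 on this array. The interferon list, with a normal mean of 7.85, stood at -1.34. The scaled 3' minus 5' level of this array was -0.741, the lowest of the 8 arrays, where RNA degradation would raise it. The 3' level is the brighter one, by 0.633 in both groups, so lower contrast could itself lower this value. The test therefore cannot decide on degradation. No biological explanation was tested, and what lowered the contrast stays open.

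Further single animals far from their group were the following, given as values. The heme and iron list was lowest in normal replicate 2 (0.870). Camk2a and Gstt3 were lowest in normal replicate 1 (0.913 and 0.921). Hemgn was highest in high-fat replicate 1 (0.854), Slc4a1 lowest in normal replicate 2 (0.886) and Klf1 lowest in high-fat replicate 2 (0.872). Xcl1 was highest in high-fat replicate 4 (0.926), while Retnla and Blk were highest in high-fat replicate 2 (0.982 and 0.849). Hdc was lowest in normal replicate 2 (0.881). The neutrophil minus lymphocyte value was highest in high-fat replicate 4 (0.873).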

How the results depend on the processing

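Scaled levels, the SD filter, the list without Xpo7, the component covariate and centring without high-fat replicate 4 were chosen after seeing the data, and a floor for linear values was not run because the deposited values are logarithmic. Except where named, the cause of a change was not tested. The count of probe sets past the threshold stayed at 0 under every alternative but 2. For the further requirement of 1.5-fold this was fixed, since it only filters the main count of 0. Rank products gave 250 (146 higher, 107 lower, 3 of them counted both ways), by a method that called many unshifted probe sets in simulated data. Its direction rests on ranks, not means. Some of its lower calls had a higher mean in the high-fat group, such as Cebpb (0.00429) and Clec4a3 (0.00326). Welch's test gave 0, and 623 probe sets at an unadjusted p under 0.05. Quantile normalization on top gave 32 (9 higher, 23 lower). The lists shifted by camera were 7, against 4 with quantile normalization (the interferon and cytotoxic lists of the 7, plus monocyte and splicing genes), 19 with centring, 0 with an estimated correlation, 0 with fry, and 3 to 10 when 1 animal was left out (3 without high-fat replicate 4). Correlations between the deviations of animals with the same number were -0.121, 0.197, 0.355 and 0.140. As only 3 of 4 were over 0.1, the numbers were not taken to pair animals, but 5 of 8 arrays correlated best with their own number, a hint from the data and not from the design. The replicate block gave 0 probe sets and 11 lists, adding monocyte (0.448), B cell (-0.563), class II (-0.890) and autophagy genes (0.384) to the 7.

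Array medians spanned 2.17e-04, and 8.19e-05 without high-fat replicate 4. Centring moves every difference by -6.60e-05, or -3.13e-05 without that animal, so a turned sign says only that a difference was smaller than this shift. Of the 47 named genes it turned 21, and 13 with that animal left out of both values. It also put the median members of called lists below 0: interferon (-0.977), erythroid (-0.213), heme (-0.968), heat shock (-1.09) and cholesterol synthesis (-1.19). Of its 19 called lists, 18 had a median below 0. These medians carry the shift, and the span of array medians exceeded 98.2% of probe set SDs. Camera can then favour lists of large spread, so calls kept, lost or turned with centring decide little. The erythroid list difference ranged from 0.00160 to 0.00754 with 1 animal left out, and its exact p was over 0.05 without any 1 of the normal animals (0.257 to 0.343). The difference itself stayed there at 0.00576 to 0.00617, and all 4 high-fat animals lay above all normal ones, so that loss does not show a smaller difference. It was 0.00252 as a mean over all probe sets (exact p 0.0571), 0.553 scaled (exact p 0.143) and 7.48e-04 without Xpo7 (exact p 0.0857). Neutrophil minus lymphocyte ranged from -6.46e-04 to 3.30e-04 and the 3' minus 5' difference from -5.10e-07 to 4.40e-06. Counts of lists differing by mean level were 0 in each setting run (quantile, centring, leaving out animals, mean over probe sets, scaled), which the smallest exact p all but fixes.

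None of the 47 named genes passed under any alternative run with limma (smallest adjusted p 0.0875). Of their 817 values there, 770 kept their direction, 20 went to about 0 and 27 turned sign without a call. Rank products, not among these values, called some of the named genes, among them Gstt3, Hemgn, Cmpk2 and Urod. Centring turned Camk2a to -3.75e-05, Plod1 -2.38e-05, Kcnab2 -5.08e-05, Shox2 -5.98e-05, Isg20 -1.08e-05, Rsad2 -3.87e-05, Slc4a1 -2.47e-05, Xcl1 -1.72e-06, Klrk1 -4.87e-05, Ireb2 -5.65e-05, Dnajb1 -1.48e-05, Dnaja1 -2.38e-05, Mvk -5.23e-05, Srebf2 -6.05e-05, Sc5d -4.68e-05, Arg1 -6.11e-05, Vcan -3.17e-05, Cx3cr1 -5.52e-05, Prg2 -4.41e-05, Hdc -4.67e-05 and Fgg -4.21e-05. Quantile normalization turned Nrxn2 to 1.67e-05, Eaf1 4.32e-06, Cmpk2 -6.53e-06, Hemgn -0.00142, Klf1 -2.81e-04 and Dnaja1 -4.05e-05. Lists whose direction relative to other genes turned by camera, given by their median within-group SDs, which need not change sign, were inflammatory genes (-1.18) and class II genes (-0.439) with centring, oxidative phosphorylation (-0.686) and splicing (-0.741) without normal replicate 3 (up to 0.257 and 0.315 without another animal), and, with medians close to 0, cholesterol synthesis (6.28e-12) and splicing (-1.81e-12) with quantile normalization.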

Other observations

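The spread measures and the tests in this part were chosen after seeing the data, except the counts over splits for lists, for rank products and for the component covariate. Several lists of blood cells and pathways were over-represented among the genes with the largest spread over all 8 animals. Among the 142 genes with the largest SD over the 8 arrays (1% of 14217), cytotoxic genes had the smallest p, with 9 of 24 members (Klrb1a, Nkg7, Prf1, Gzma, Gzmb, Gzmk, Gzmm, Il2rb and Ccl5) where 0.240 were expected (Fisher's exact test, adjusted p = 3.35e-11 over 38 lists). Class II antigen presentation followed with 5 of 10 where 0.0999 were expected (Cd74 and 4 RT1 genes, adjusted p = 4.26e-07) and the erythroid list with 6 of 23 (Hba-a3, Ahsp, Gypc, Rhd, Hemgn and Xpo7, adjusted p = 9.93e-07). The interferon response had 5 of 33 (Ifit1, Ifit2, Isg15, Irf7 and Ifi27, adjusted p = 1.67e-04), monocytes 4 of 21, neutrophils 4 of 22 and endoplasmic reticulum stress 3 of 24 (adjusted p = 3.80e-04, 3.84e-04 and 0.00919). Single animals carry much of this spread: of the 30 genes with the largest SD, 19 were highest in high-fat replicate 4 and 7 in high-fat replicate 1. Genes of a cell type move together, so these p-values are too small, and a deposited SD also depends on how each probe set was compressed.

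The widest single ranges belonged to Xpo7 (0.408), Ldhb, a subunit of lactate dehydrogenase (0.204), Tmcc2 (0.190) and the interferon-induced Ifi27 (0.0756). Xpo7 and Tmcc2 were both highest in high-fat replicate 1. Ldhb was at 6.83 in normal replicate 1 and between 6.97 and 7.04 in the 7 other animals. Their unadjusted limma p were 0.216, 0.962, 0.225 and 0.105. Rank products had all 4 among its calls, and on this probe set the high-fat values of Xpo7 all lay above the normal ones. A second probe set of Xpo7 was 0.00387 higher in the high-fat group, or 0.660 within-group SDs, with overlapping groups.

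Counts of calls were set against all 35 ways to split the 8 arrays into 4 and 4. No split gave any probe set past the threshold (highest other 0). With a real count of 0, 35 of 35 splits give as many by definition, so nothing about chance follows. As many probe sets at an unadjusted p under 0.05 as the real 699 came from 34 of 35 splits, the highest other being 5095. For camera, 24 of 35 splits gave at least the real 7 lists, and the highest other gave 18. For rank products 28 of 35 gave at least the real 250, with a highest other of 1134. Chance could not be excluded for these 3 counts. With the first within-group component as a covariate the real count was also 0, which 35 of 35 splits reach by definition, and the highest other gave 640. The split of replicates 1 and 3 of both diets against replicates 2 and 4 gave the highest unadjusted count, list count, rank product count and covariate count. The unadjusted and rank product counts were several times the real ones, which points to a structure of the arrays that does not follow the diet.

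After quantile normalization on top of the deposited values, 10 of 35 splits gave at least the 32 probe sets of the real one (highest other 189), so chance could not be excluded there either. A hypothesis is that these calls are rank steps left by near-identical arrays. Of the 32, 30 had a within-group SD of 0 after the normalization, which is consistent with that. Of the same 32, 12 lay between the lowest level of Xpo7, 8.45 in normal replicate 1, and 8.48. The latter was its highest level in the high-fat animals other than replicate 1. In this range a single gene changing rank shifts all genes it passes.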
